A study of Mus musculus with 6 samples.

How the data were processed

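RNA from 6 samples of mouse inner medullary collecting duct (IMCD) cells was measured on Affymetrix whole-transcript arrays, with 1 biotin-labelled array per sample. The labels place 3 arrays in a wild-type ILK group and 3 in an ILK-T173I group, and call the 3 of each group biological replicates. How the stable lines relate to the replicates is not given in the sources used here. The p-values below measure the spread between these arrays. Per the labels' protocols, total RNA was purified with a Qiagen kit and amplified and labelled with the WT PLUS kit.

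The deposited table holds log2 values that the authors made with RMA, per the submitters' processing notes. RMA corrects background, normalizes the distribution of probe signals across arrays and summarises the probes of each probe set on the log2 scale. Its implementation, version and probe set definition are not given in the sources used here. The scale was checked against the values, which ran from 0.873 to 13.7 and had array medians of 5.45 to 5.52. Because RMA makes the arrays' signal distributions alike, a shift of most transcripts in one direction would not be seen. Array signal has no read depth, and the number of arrays limits the precision. The scanner files were not used here.

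The table has 41345 probe sets. The platform annotation lists 25335 of them, of which 23521 have 1 gene symbol and 1814 have several. The other 16010 are unnamed here. No gene was named from a probe set with several symbols, which leaves some genes without a value, Ilk among them. Gene symbols are those of the platform annotation. Of its 23521 probe sets with 1 gene symbol, 23328 had an Entrez identifier found in the mouse gene table of assembly GRCm38.p6, which was used only for names. For the 1082 genes with several probe sets, the one with the highest mean over all 6 arrays stood for the gene. This gave 22180 genes. The 40% with the lowest mean over all arrays (log2 5.37 or less) were left out, and 13308 genes were tested.

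The comparison of T173I with wild type was fitted with limma (version 3.58.1, R 4.3.3) using lmFit and eBayes over all 6 arrays, with no covariate and tests of both directions. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. Intervals are 95% intervals of the fit. Differences are T173I minus wild type in log2 units. A set of 30 gene lists was tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 30 lists. The lists, the limma and camera tests, the filter and the rule for named genes were fixed before the data were examined. Members of a list were also given Benjamini-Hochberg values over the tested members of that list alone, with the same threshold. These values were not corrected across the 30 lists. They are not counted among the tests fixed beforehand, and members past the threshold only in this way are descriptive. The exact permutation test of 3 arrays against 3 cannot give a p below 0.1.

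The rule for named genes took up to 12 genes in each direction with the largest change among genes past the adjusted threshold. If fewer than 8 passed, which was so, it took the 12 with the smallest unadjusted p in each direction and a change of at least 1.5-fold, said not to pass. Predicted genes and RNA genes were not named. The rule added Egfr, and from each list up to 4 members with the smallest unadjusted p.

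The scripts were tested on simulated data with the means and spread of the 13308 genes and 200 genes changed. With the pooled spread of both groups and 3 arrays against 3, limma recovered 80% of 100 genes changed 2-fold and 97% of 100 genes changed 4-fold, with 11 false calls. With 3 arrays against 2, it recovered 71% and 90%. The simulation draws genes independently, which real arrays do not. In a simulation of the gene lists with independent genes, camera called the 1 list shifted by 0.5 and 1 of the other 29.

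Same-numbered arrays did not deviate together. Over the tested genes, the correlation of their deviations from the group means was 0.049 for replicate 1, 0.067 for replicate 2 and 0.048 for replicate 3, so the numbers were not treated as pairs. No arrays held the same values throughout, but single genes did: of the 13308 tested genes, 97 had exactly equal values on all 3 wild-type arrays and 47 on all 3 T173I arrays, and 2640 had some equal pair among the 6 arrays. Such ties lower the spread that a test sees; their cause was not tested. Alternatives covered the filter, the eBayes prior, the normalization between arrays, the probe set rule, array weights, the replicate block, the set test and leaving out each array.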

Results

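Gene expression was compared between 2 groups of stably transduced mouse IMCD cells, an epithelial cell model of the kidney collecting duct. The cells carried a lentiviral vector encoding GFP together with either wild-type ILK or the missense variant T173I. ILK, integrin-linked kinase, is a scaffold of focal adhesions that links integrins to the actin cytoskeleton. All cells had received EGF at 20 ng/ml for 15 minutes and were harvested after 1 hour of further incubation. Each group had 3 arrays, and the arrays had median log2 signals of 5.45 to 5.52. All 6 arrays were EGF-stimulated and carried an ILK vector, so the comparison addresses which genes differ between the groups under EGF, not the response to EGF or to ILK itself. The number of lines behind each group is not given in the sources used here, and with 1 line per group, line and variant could not be told apart.

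The level of Ilk RNA could not be read on its own. No probe set in the annotation belongs to Ilk alone, and the 3 that list it also list a neighbouring gene, Taf10 or Rrp8. Probe set 17481460, listed for Taf10 and Ilk, had a log2 signal of 10.4 ± 0.16 (SD, n = 3) in wild type and 10.3 ± 0.29 (SD, n = 3) in T173I. Probe set 17494588, listed for the same 2 genes, had 8.61 ± 0.14 and 8.59 ± 0.081. Probe set 17494576, listed for Rrp8 and Ilk, had 8.13 ± 0.030 and 8.28 ± 0.36. None of these differences exceeded the spread between arrays (exact two-sided permutation p = 0.7, 0.9 and 0.7, where 0.1 is the smallest possible). Which species the introduced ILK sequence came from is not given, so whether these signals include the transgene is unknown. T173I replicate 1 had the lowest signal of the 6 arrays on probe sets 17481460 (10.04) and 17494576 (8.003), and T173I replicate 2 had the highest (10.62 and 8.68).

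The arrays of the T173I group were less alike than those of the wild-type group. Pearson correlations over the 13308 tested genes were 0.989 to 0.993 between wild-type arrays and 0.964 to 0.983 between T173I arrays. The median SD of a gene was 0.098 log2 units in wild type and 0.16 in T173I. The first principal component held 57.4% of the variance. T173I replicates 2 and 3 had values of 38.3 and 15.8 on it, while T173I replicate 1, at -11.4, lay among the wild-type arrays at -18.3 to -11.3. T173I replicate 1 stood apart from the wild-type arrays on the second component, which held 15.3% of the variance. T173I replicate 3 correlated about as well with wild-type replicate 3 (0.9825) as with T173I replicate 2 (0.9830). T173I replicate 2 had the highest median signal, 5.52 against 5.45 to 5.48 on the other arrays.

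**Figure D1:**
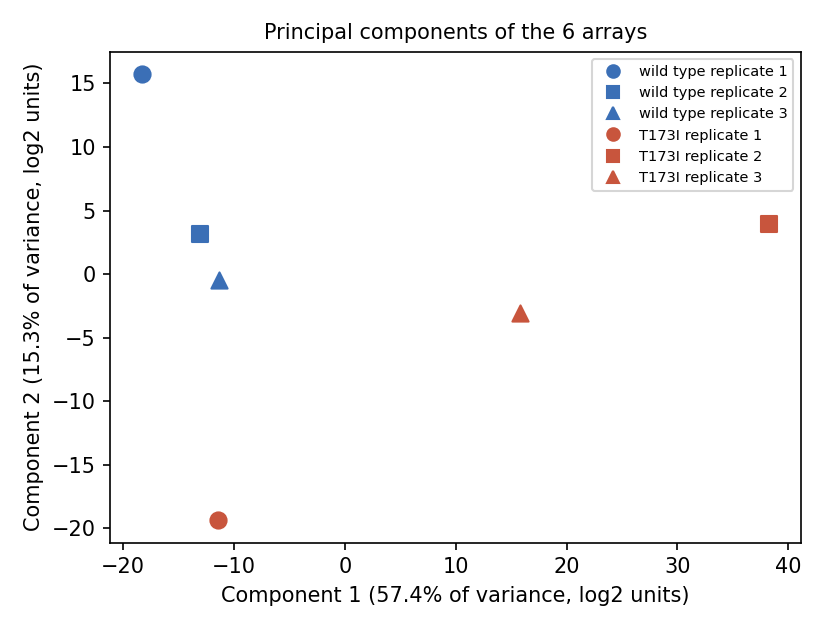
First and second principal components of the 13308 tested genes, in log2 units, with 1 point per array; colour gives the group and marker shape the replicate. T173I replicate 1 lies at -11.4 on the first component with the wild-type arrays, and T173I replicates 2 and 3 lie at 38.3 and 15.8.

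The 24 leading genes, 12 in each direction, differed between the groups by up to 5.08-fold, and none passed the adjusted threshold. The largest difference among the 12 higher genes was that of Etv4, an Ets transcription factor of branching epithelia, at 5.70 ± 0.067 (SD, n = 3) in wild type and 7.02 ± 0.46 (SD, n = 3) in T173I, a 2.49-fold difference. Il18r1, a subunit of the interleukin-18 receptor, was 2.19-fold higher. Tnfrsf21, a death-domain receptor, was 2.03-fold higher, and Il34, a ligand of the CSF1 receptor, was 1.87-fold higher. Ak4, a mitochondrial adenylate kinase, and Adm2, a peptide of the adrenomedullin family, were higher by 0.84 and 0.82 log2 units. Tgfb1i1, a LIM-domain protein of focal adhesions, was higher by 0.77 and Ccng1, a p53-induced cyclin, by 0.59. The others were Sytl2, Pqlc3, Prcp and Mpzl3, with differences of 0.65 to 0.93.

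Among the 12 leading lower genes, Plxdc2, a transmembrane protein, was at 7.80 ± 0.59 (SD, n = 3) in wild type and 5.46 ± 0.55 (SD, n = 3) in T173I, a 5.08-fold difference. Gulp1, an engulfment adaptor, was 4.01-fold lower. Antxr1, a receptor that binds extracellular matrix, was 2.71-fold lower, and P2ry1, a purinergic receptor for ADP, was 2.08-fold lower. Cdkn1c, an inhibitor of cyclin-dependent kinases, had a difference of -0.72 with a 95% interval of -0.91 to -0.53. Ahr, the aryl hydrocarbon receptor, had a difference of -0.79, and Arhgef10l one of -0.65. Gata3, a transcription factor of the collecting duct, had a difference of -0.78 on the brighter of its 2 probe sets and the opposite sign on the other. Triqk, Cfap20dc, Smpdl3a and Ppm1h had differences of -1.27 to -0.60. In all 24 genes the T173I arrays, replicate 1 included, lay on 1 side of the wild-type arrays; the rule chose these genes by p, which favours such genes.

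In limma's test over 13308 genes, 0 had an adjusted p under 0.05, and the lowest adjusted p was 0.34. At an unadjusted p under 0.05 there were 1357 genes, 650 higher and 707 lower in T173I, where 665 would be expected by chance. That count was 670 without wild-type replicate 1, 795 without wild-type replicate 2 and 2946 without T173I replicate 1. Of the 1357 genes, 365 differed by at least 1.5-fold. In 15.2% of genes the 2 groups did not overlap, where chance gives 10%. Without T173I replicate 1, 156 genes passed, 91 higher and 65 lower, and 151 of them by at least 1.5-fold, while leaving out any other array gave 0.

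**Figure D2:**
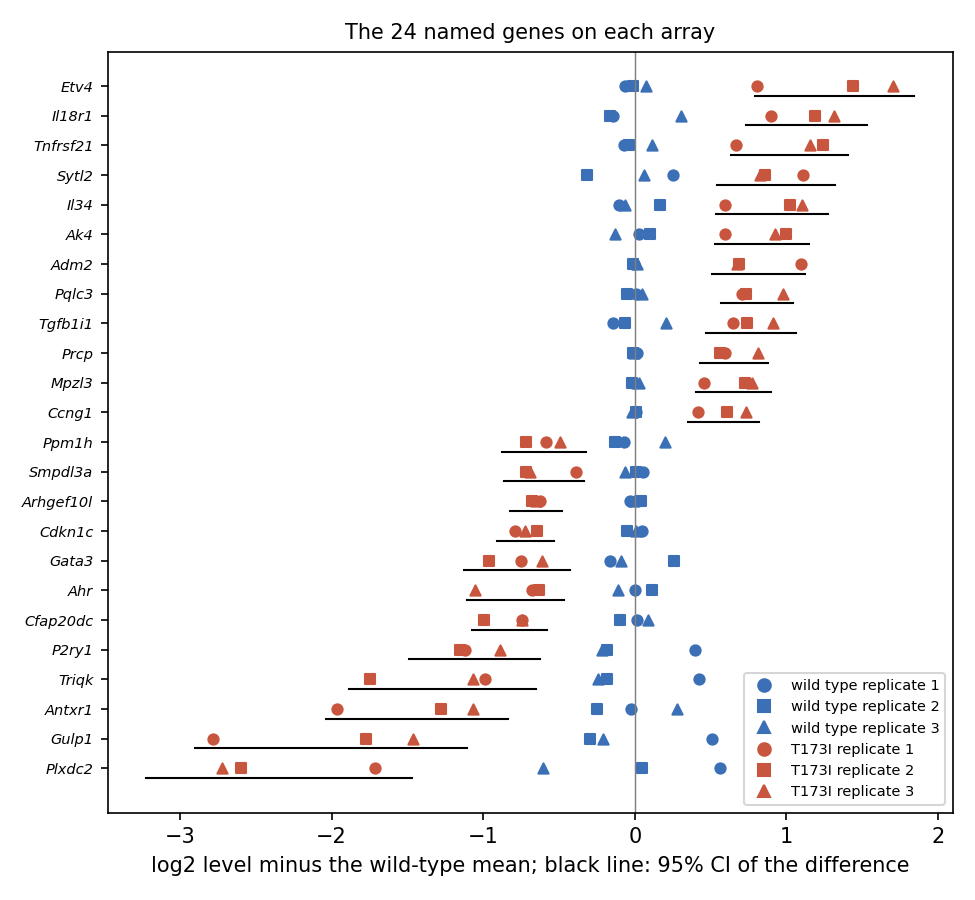
The 24 leading genes, with each array's log2 level minus the wild-type mean on the x axis and 1 point per array; black lines are 95% intervals of the difference from limma. The T173I arrays lie to one side of the 3 wild-type arrays for each gene, from Plxdc2 at -2.34 to Etv4 at 1.32.

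Genes that act as feedback inhibitors and outputs of ERK signalling, the kinase cascade downstream of the EGF receptor, were shifted upwards as a list. Of 25 tested members 23 had positive differences, with a median of 0.47 log2 units. Ccnd1, which encodes cyclin D1, was 5.77-fold higher, a difference of 2.53 with a 95% interval of 0.64 to 4.42. Ccnd1 was at 7.71 on T173I replicate 1, just above the wild-type range of 6.27 to 7.68, and at 10.76 and 10.10 on replicates 2 and 3. Without T173I replicate 1 its log2 fold change was 3.43. Etv5, an Ets factor related to Etv4, was higher by 1.67 and Plaur, the urokinase receptor, by 1.41. Only Etv4 passed when adjusted over the list alone, and 0 members passed over all genes tested. The list had a camera adjusted p of 3.9e-06, and its call was lost with an estimated correlation (adjusted p = 0.55). Its mean level, relative to the wild-type mean, was 1.08 on T173I replicate 2, 0.66 on replicate 3 and 0.063 on replicate 1, against -0.10 to 0.11 on the wild-type arrays (exact two-sided permutation p = 0.2 for the mean of the list, where 0.1 is the smallest possible).

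The immediate early genes of the EGF response, induced within the first hour and many of them transcription factors, had members on both sides. Egr1 fell by 0.55, Jun by 0.57 and Fos by 0.69, and Srf, the serum response factor, rose by 0.42. These 4 of 25 members passed when adjusted over the list alone, and 0 over all genes tested. The list as a whole was not shifted (camera adjusted p = 0.76), with a downward direction, a median of -0.014, a mean of 0.0069 and 12 members positive. The list of ErbB receptors and adaptors was not shifted either (camera adjusted p = 0.77), nor did any of its 19 members pass. Egfr, the EGF receptor, was at 10.7 ± 0.059 (SD, n = 3) in wild type and 10.5 ± 0.44 (SD, n = 3) in T173I, a difference of -0.26 with a 95% interval of -0.76 to 0.24. The log2 fold change of Egfr was -0.41 without T173I replicate 1 and -0.0077 without T173I replicate 3. Map2k1, an ERK pathway kinase, was higher by 0.26 and Lrig1, an inhibitor of ErbB receptors, had a difference of -0.45.

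Genes of epithelial structure, matrix and mesenchyme were shifted upwards as 3 lists at camera's preset correlation. With an estimated correlation the 3 calls were lost (adjusted p = 0.55 each). In the epithelial junction and polarity list, 4 of 31 members rose when adjusted over the list alone and 0 over all genes tested. These were the keratins Krt19 (by 1.62), Krt8 (by 0.64) and Krt18 (by 0.44), intermediate filament proteins, and Ovol1 (by 0.79), an epithelial transcription factor. None of the 4 encodes a junction protein. The list's camera adjusted p was 0.014, and its call was lost without wild-type replicate 3 (adjusted p = 0.057) or T173I replicate 3 (0.25). The mean of the list on T173I replicate 2 was 0.015, within the wild-type range of -0.048 to 0.035. Of 26 extracellular matrix genes 19 had positive differences (median 0.15), among them Fn1, fibronectin, higher by 0.97, and the laminin chains Lamb3 and Lama3, higher by 1.26 and 0.79. Of 13 tested mesenchymal genes 10 had positive differences (median 0.32). Acta2, smooth muscle actin, was at 7.53 ± 0.39 (SD, n = 3) in wild type and 9.66 ± 1.93 (SD, n = 3) in T173I, and S100a4 was higher by 1.09. Acta2 was at 7.92 on T173I replicate 1, within the wild-type range of 7.27 to 7.98, and at 11.74 and 9.33 on replicates 2 and 3. Without T173I replicate 2 the log2 fold change of Acta2 was 1.09 and the log2 fold change of S100a4 was 0.57. Without T173I replicate 1 the log2 fold change of Lamb3 was 1.89 and the log2 fold change of Lama3 was 1.22; the former was 0.84 without T173I replicate 2 and the latter 0.53 without T173I replicate 3. The matrix and mesenchymal lists had camera adjusted p of 0.014 and 0.016, and no member passed when adjusted over the list alone or over all genes tested. Both lost their call without T173I replicate 2 (adjusted p = 0.14 and 0.12) or wild-type replicate 1 (0.11 and 0.077), and without the filter on dim probe sets (0.15 and 0.31). A stricter filter ended the mesenchymal call (0.067) and array weights the matrix call (0.089). The mean of the mesenchymal list was 0.043 on T173I replicate 1, within the wild-type range of -0.22 to 0.25. A list of fibroblast and stromal markers was not shifted (camera adjusted p = 0.94), with a downward direction, a median of -0.0098 and a mean of 0.13. It shares Acta2 and other members with the mesenchymal list, and collagen genes and Postn with the matrix list.

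Genes of p53 signalling, hypoxia and glycolysis, and the NRF2 antioxidant response were shifted upwards at the preset correlation. With an estimated correlation the 3 calls were lost (adjusted p = 0.55 each). In the p53 and apoptosis list, of which 14 of 21 members had positive differences, Ccng1, Perp and Plk3 rose by 0.59, 0.59 and 1.01 when adjusted over the list alone, 3 of 21 members, with 0 over all genes tested. Mdm2, the ubiquitin ligase that restrains p53, was higher by 0.47. The list's camera adjusted p was 0.0069, and 0.55 with an estimated correlation. In the hypoxia and glycolysis list 20 of 24 members had positive differences, and P4ha1, a collagen prolyl hydroxylase, rose by 0.90 when adjusted over the list alone, the only member to do so, with 0 over all genes tested. Ldha, Pgk1 and Hk2, enzymes of glycolysis, were higher by 0.34, 0.44 and 0.88. The list's camera adjusted p was 0.0012, and 0.55 with an estimated correlation. Its mean was highest on T173I replicate 1, at 0.33, with 0.046 on replicate 2 and 0.18 on replicate 3. The wild-type arrays lay at -0.018 to 0.025. Without T173I replicate 1 the camera adjusted p was 0.0496. In the NRF2 list 12 of 18 members had positive differences, among them Gclm, a subunit of the glutathione-synthesising ligase, higher by 0.46, and Me1, malic enzyme, by 0.60. No member passed either adjustment, and the list's camera adjusted p was 0.0069. That call was lost with an estimated correlation (adjusted p = 0.55), without T173I replicate 1 (0.068) and with array weights (0.082). The mean of the NRF2 list on T173I replicate 2 was 0.14, within the wild-type range of -0.21 to 0.1795. Replicate 3, at 0.1796, lay at the upper end of that range, and replicate 1, at 0.30, above it.

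Genes of DNA replication, interferon response and oxidative phosphorylation were shifted downwards at the preset correlation. With an estimated correlation the 3 calls were lost (adjusted p = 0.61 each). Of 37 replication and G1/S genes 29 had negative differences (median -0.14), among them Mcm7, a subunit of the replicative helicase (-0.34), and Rfc3, a clamp loader subunit (-0.35). The mean of the list was 0.0085 on T173I replicate 1, within the wild-type range of -0.068 to 0.053, against -0.30 and -0.13 on replicates 2 and 3. Of 28 interferon-stimulated genes 22 had negative differences (median -0.30), among them Gbp3 (-0.74), Ifit2 (-0.72) and Parp14 (-0.51). Without T173I replicate 2 the log2 fold change of Parp14 was -0.32. Of 29 oxidative phosphorylation genes 26 had negative differences (median -0.063), Cox5b, a subunit of cytochrome oxidase, having -0.40. Camera adjusted p was 0.0021, 0.0069 and 0.031, and 0.61 for each with an estimated correlation, and no member passed either adjustment. The mean of the interferon list was -0.70 on T173I replicate 2, while replicates 1 and 3 (-0.19 and -0.17) lay within the wild-type range of -0.23 to 0.25. The oxidative phosphorylation list was within its wild-type range on T173I replicate 1 (-0.028). The interferon call was lost without T173I replicate 2 (adjusted p = 0.13) or wild-type replicate 1 (0.086). The oxidative phosphorylation call was lost without the same 2 arrays (0.14 and 0.086) or wild-type replicate 2 (0.053). Ribosomal protein genes were shifted upwards by a median of 0.039 (camera adjusted p = 0.046, and 0.61 with an estimated correlation). That call was lost without 4 of the arrays, wild-type replicates 2 and 3 and T173I replicates 2 and 3, with adjusted p of 0.053 to 0.34. Array weights ended the interferon (adjusted p = 0.32), oxidative phosphorylation (0.089) and ribosomal (0.073) calls. Repeated quantile normalization (0.070) and cyclic loess (0.052), the latter chosen after seeing the data, ended the oxidative phosphorylation call, and either no filter (0.065) or a stricter one (0.083) the ribosomal call.

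In all, camera at the preset correlation called 11 of 30 lists, 8 upwards and 3 downwards, and with an estimated correlation it called 0, as did fry. At an unadjusted p under 0.05 the estimated correlation gave 0 lists and fry gave 5. The other splits of the 6 arrays into 3 and 3 called 3 to 12 lists at the preset correlation.

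**Figure D3:**
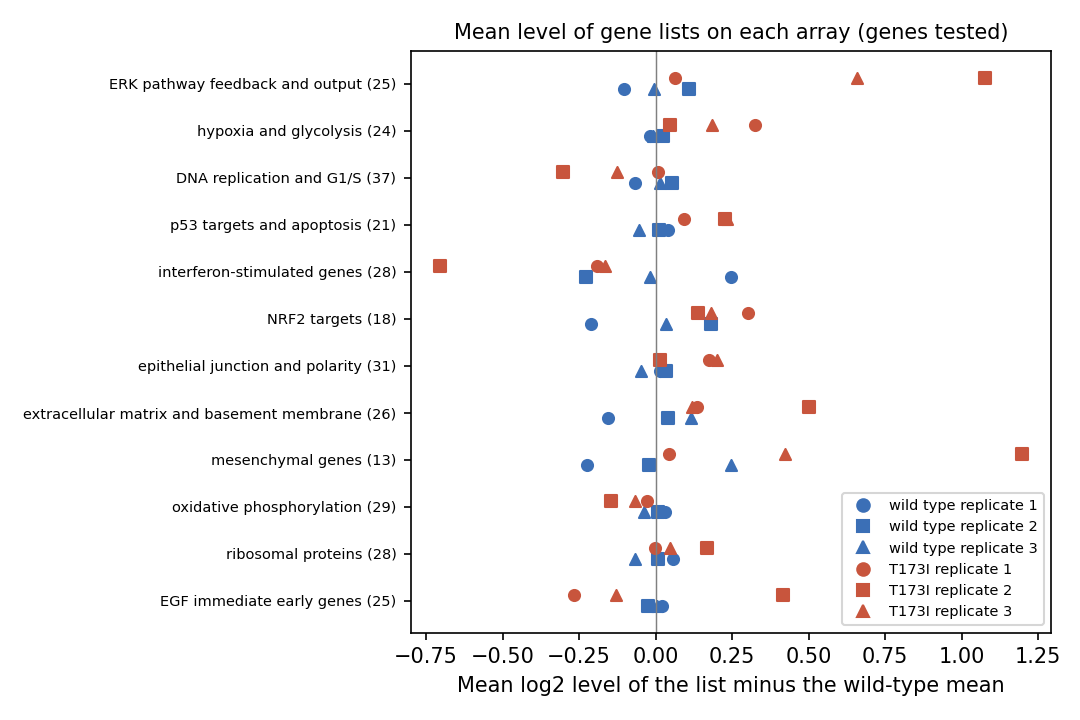
Mean log2 level of each gene list on each array minus the wild-type mean, for the 11 lists called by camera and the EGF immediate early list; numbers in brackets count the genes tested. T173I replicates 2 and 3 lie at 1.08 and 0.66 for the ERK list, and T173I replicate 1 at 0.063.

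The remaining lists were not called. Of the integrin and focal adhesion list, 6 members were higher and 4 lower at an unadjusted p under 0.05, and Tgfb1i1 rose by 0.77 when adjusted over the list alone, 1 of 31 members. Itgb6 and Itga2, integrin subunits, had differences of -0.98 and -1.28, and Itgb3 one of 0.39. The list's camera adjusted p was 0.52 with an upward direction, a median of 0.061 and a mean of -0.044. Of 27 ureteric bud and branching genes, Etv4 rose by 1.32, and Gata3 and Fras1, an extracellular matrix protein, fell by 0.78 and 1.01 when adjusted over the list alone. Fgfr2, a fibroblast growth factor receptor of the ureteric bud, had a difference of -1.30. That list's camera adjusted p was 0.23. Among YAP/TEAD targets Dock5 rose by 0.90, and in the osmotic stress list Nfat5, the tonicity-responsive transcription factor, fell by 0.43, each the only member past the threshold when adjusted over the list alone. In each of these 4 lists 0 members passed over all genes tested.

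Markers of the principal cell, the main salt- and water-transporting cell of the collecting duct, did not pass over all 6 arrays (camera adjusted p = 0.086, 8 of 12 members negative). The mean of the list was 0.022 on T173I replicate 1 and -0.50 and -0.43 on replicates 2 and 3. Without T173I replicate 1 the list was called downwards (adjusted p = 0.0072, and 0.63 with an estimated correlation). Gata3 alone fell in that list when adjusted over the list alone, with Scnn1g, a sodium channel subunit, at -1.19. Without T173I replicate 1 the log2 fold change of Scnn1g was -1.80. Intercalated cell markers (camera adjusted p = 0.22), proximal tubule markers (0.69) and loop and distal tubule markers (0.55) were not shifted, and none of their members passed. In the list of immune and endothelial markers, of which 9 of 21 were tested, Cd68 rose by 1.10 and Cd14 and Csf1r fell by 1.37 and 0.78, and Tyrobp fell to a level below that used to leave out dim genes, when adjusted over the list alone, with 0 over all genes tested. The list as a whole was not shifted (camera adjusted p = 0.089). The G2/M list (0.079), the primary cilium list (0.081, and 0.049 downwards without T173I replicate 1, where an estimated correlation gave 0.74), the NF-kB list (0.083), the cholesterol synthesis list (0.089), the TGF-beta and Wnt target lists (0.11 each), and the unfolded protein list (0.76) were not called. In the last, Asns, asparagine synthetase, was higher by 0.71. Camera's direction for that list was upward, with a mean of 0.059 and a median of -0.073, and for the ErbB list upward with a mean of -0.0046 and a median of -0.012.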

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

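The count of 0 genes past limma's adjusted threshold held without a filter on dim probe sets, with a stricter filter, with an intensity trend or robust prior, after repeated quantile normalization, median centring or cyclic loess, with the mean of a gene's probe sets, with every probe set tested separately, with array weights and at an adjusted p under 0.1; the same holds for the count at 1.5-fold where it was computed. At an unadjusted p under 0.05 the count was 1357, and 670 to 2946 leaving out 1 array. Leaving out 1 array gave 0 to 156 genes, 0 to 151 at 1.5-fold and 9 to 12 lists; every nonzero count of genes came without T173I replicate 1. After cyclic loess, chosen after seeing the data, leaving out that array gave 175 genes. Camera with an estimated correlation and fry each called 0 lists where the preset correlation called 11, and camera with an estimated correlation also called 0 without T173I replicate 1, an alternative chosen after seeing the data. The estimated correlations were up to 0.65 against the preset 0.01. The replicate block gave 0 genes and 9 lists, and ended the calls of the ribosomal (adjusted p = 0.073) and oxidative phosphorylation lists (0.055); wild-type replicate 1 correlated better with T173I replicate 3 than with its own number. Without the filter the matrix (adjusted p = 0.15), mesenchymal (0.31) and ribosomal (0.065) lists lost their calls, and a stricter filter ended the mesenchymal (0.067) and ribosomal (0.083) calls; array weights called 8 lists, without the matrix, interferon, NRF2, ribosomal and oxidative phosphorylation lists. The oxidative phosphorylation call was also lost on repeated quantile normalization (adjusted p = 0.070) and cyclic loess (0.052). The cause of these losses was not tested. Of 2150 values of the 137 named genes under alternatives, 2116 kept their sign and side of the threshold, 27 passed it without T173I replicate 1, and 7 changed sign, in 3 distal tubule genes with differences near 0. With array weights the log2 fold change of Cldn19 was -0.041 and the log2 fold change of Pvalb was -0.0069. Leaving out 1 array, the log2 fold change of Cldn19 ran from -0.045 to 0.12, the log2 fold change of Pvalb from -0.040 to 0.063 and the log2 fold change of Kcnj10 from -0.064 to 0.0075. No set test was run with the robust prior, and no alternative was run for Ilk, which has no probe set of its own. No scaling moved the median difference of all genes by more than 0.1. Genes in the dimmest 40% were tested only without the filter and with every probe set tested separately.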

Other observations

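Without T173I replicate 1, the genes past limma's adjusted threshold outlined a difference between T173I replicates 2 and 3 and the wild-type arrays. These genes were chosen for naming after their values were seen, and this array is the only one of the 6 whose omission gave any call. Ccnd1, a D-type cyclin gene, rose by 3.43 (SE 0.43). Krt20, a keratin of differentiated epithelia, rose by 3.79, and Etv5 and Etv4 rose by 2.33 and 1.57. Ccnd2, another D-type cyclin gene, and Ptpn22, a tyrosine phosphatase, also passed, but their wild-type means of 4.60 and 4.97 were below the level used to leave out dim genes, so the sizes of their differences are not given. Ccnd2 was at 9.72 and 8.28 on T173I replicates 2 and 3, and Ptpn22 at 7.94 and 7.70. Lamb3 and Lama3, chains of the epithelial laminin, rose by 1.89 and 1.22. Tns1, the focal adhesion protein tensin, was at 8.70 in wild type and at 5.26 and 5.37 on T173I replicates 2 and 3, whose mean was below the level used to leave out dim genes; it is the 1 gene of the 156 with exactly equal values on all 3 wild-type arrays, which makes its error too small. Itga1, an integrin subunit, fell by 1.53, Fgfr2 fell by 1.75 and Bmp4, a growth factor, fell by 1.70. Scnn1g, a subunit of the collecting duct sodium channel, fell by 1.80 and Muc1, an apical mucin, by 1.94. On T173I replicate 1 itself, Ccnd2 was at 4.57. Relative to the wild-type mean, Tns1 was at 0.72 and Itga1 at 0.65 on that array, while Krt20 was at 1.88 and Plxdc2 at -1.71. Over the 200 genes that best part wild type from T173I replicates 2 and 3, replicate 1 lay beyond a pair of wild-type arrays, in the direction of the others, on 61.5% to 73% of genes, against 32% to 64% for a left-out wild-type array. On 4 of all tested genes, all 3 T173I arrays lay over 1 log2 unit beyond the 3 wild-type arrays, and these were Krt20, Plxdc2, Gulp1 and Depp1.

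The tests of T173I replicate 1's position, of its outlying genes, of the immediate early list and of the splits by genes, and the cyclic loess setting, were chosen after the result was seen. With 10 splits of 6 arrays no share under 0.05 can be had. The real split gave 0 genes and the highest other 1, also at 1.5-fold, so that all 10 splits gave as many. The real split called 11 lists and the highest other 12, with 3 splits calling as many. At an unadjusted p under 0.05 the real split gave 1357 genes and the highest other 1491, with 2 splits giving as many. That other split exchanged T173I replicate 1 and wild-type replicate 3. Of the 10 splits of the 5 arrays without T173I replicate 1, the real one gave 156 genes and the highest other 1. That array was singled out because its omission alone gave calls, and it leaves replicates 2 and 3 apart from the rest. The real split was therefore favoured in advance, and its count does not bear on an effect of the variant.

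T173I replicate 1 lay nearer to the wild-type arrays than to the other T173I arrays. A scale or signal-dependent bias left in the RMA values is argued against as the cause, since 175 genes passed under cyclic loess without this array. Of these, 153 were shared with the 156 before it, and the difference did not follow mean signal (Spearman rho 0.024 across genes). Cyclic loess ran on values already normalized by RMA, so it cannot show an artefact that arose before that step. A wild-type RNA under the T173I label may account for the position of T173I replicate 1. On the axis from wild type (0) to T173I replicates 2 and 3 (1), replicate 1 was at 0.15. But measured against 2 wild-type arrays, as left-out wild-type arrays at -0.064 to 0.16 were, it was at 0.14 to 0.22. It also lay over 1 log2 unit beyond 2 wild-type arrays on 57 to 70 genes, against 4 to 30 for a wild-type array. For a mixture with wild-type RNA, the linear-scale share of RNA like that of the other T173I arrays was computed. It was 11.3% (95% bootstrap interval 8.7 to 16.7) over genes higher in those arrays. Over genes lower it was 23.96% (9.2 to 30.7). The bootstrap resampled genes, so its intervals do not measure the spread between arrays. The intervals overlap, but no share was computed for a wild-type array, so this does not tell a mixture from unmixed wild-type RNA. On 4 to 9 of the 57 to 70 genes both other T173I arrays also lay over 1 log2 unit beyond, against 2 to 7 of the 4 to 30 for a wild-type array. They lay beyond by any amount on 20 to 33, against 4 to 13. As shares of the outlying genes these were 35.1% to 49.2%, against 33.3% to 100%, so the share was no greater than for wild-type arrays. A mixture with RNA like theirs would place them further out on each such gene. The rest of the 57 to 70 genes argue against a mixture alone, though wild-type arrays had some such genes too. A difference between the T173I cultures stays open, and these arrays cannot tell whether such a difference would concern the variant. T173I replicate 1 had the lowest signal of the T173I arrays on each of the 3 probe sets that list Ilk, but none reads Ilk alone.

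The ERK output list was higher in T173I, while immediate early genes went both ways, Fos, Jun and Egr1 lower and Srf higher. At the preset correlation the list kept its upward call in each of the 6 fits without 1 array, with camera adjusted p of at most 0.0016. Its level was raised on both T173I replicate 2 (1.08) and replicate 3 (0.66), which argues against a single array as the only source. But the fit without replicate 2 and the fit without replicate 3 each kept only 1 raised array and still gave a call. These fits therefore cannot show that a call needs more than 1 raised array. With an estimated correlation the call was lost over all arrays (adjusted p = 0.55) and without T173I replicate 1 (0.72), and the list's level on T173I replicate 1 was within the wild-type range. Unequal EGF stimulation of the cultures could move ERK outputs and immediate early genes together, and the mean of the immediate early list was 0.0069, with members on both sides and levels of 0.42 on T173I replicate 2 and -0.27 and -0.13 on replicates 1 and 3. This cannot be told apart from an effect of the variant, because all arrays were taken at 1 time after EGF and no unstimulated arrays were analysed here.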
